A study of Arabidopsis thaliana with 15 samples.

How the data were processed

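RNA from the fifth rosette leaf of 21 day old Arabidopsis thaliana plants was purified on columns, selected for polyadenylated transcripts and made into sequencing libraries, per the labels' protocols. There were 15 libraries in 4 genotypes: WT, dme and rdd with 4 each and drdd with 3. Genotypes and replicate letters were taken from the labels. The labels do not say whether replicates came from separate plants, so p-values measure the spread between these libraries, which may be partly technical.

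The authors deposited a file of read counts per gene for each library. FastQC, Trim Galore, STAR, HTSeq and DESeq2 are named in the submitters' processing notes, with no version and no settings, and the genome build, the gene annotation and the strand setting are not given in the sources used here. FastQC and Trim Galore check and trim reads, STAR aligns reads to a genome across introns, and HTSeq assigns aligned reads to genes. The deposited counts were whole numbers for 37336 genes, with 5 summary lines that name no gene. These lines stayed out of library sizes and tests. Reads that met no gene made up 1.54% to 2.17% of a library and reads that met several genes 0.117% to 0.176%. The lines for unaligned, poorly aligned and multiply aligned reads held 0 in every library, so losses at those steps were not measurable here. Reads of near-identical copies that align to several places may be missing from the counts of either copy, and without a stated strand setting reads of a gene and of an overlapping or antisense neighbour cannot be told apart. Levels of such genes are therefore uncertain.

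The authors also deposited DESeq2 tables for dme, rdd and drdd against WT and for drdd against rdd. Per the file headers, these tables hold the mean signal per gene as counts divided by size factors, the log2 fold change with its standard error, the Wald statistic as a score, and the p-value with its adjusted value. The direction of each deposited log2 fold change was read from the group means in the same table. The authors' adjusted p-values were present for 17674 genes in the dme table, 20061 in the rdd table, 20427 in the drdd table and 19363 in the table of drdd against rdd. These tables served as a comparison with the counts of calls, the fold changes and single genes computed here. Across tested genes the deposited log2 fold changes and those computed here had Pearson correlations of 0.998 to 0.999.

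Differential expression was computed from the deposited counts with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a smallest group of 3 libraries, which left 18598 genes. Library sizes were scaled by TMM (factors 0.953 to 1.09), and group means were fitted in one quasi-likelihood model with robust dispersions over all 15 libraries, with 11 residual degrees of freedom and a common biological coefficient of variation of 0.266. The contrasts were dme, rdd and drdd against WT, drdd against rdd, drdd against dme, and the interaction, which is the difference between drdd and rdd minus the difference between dme and WT. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no fold threshold. The designs, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where stated. Fold differences against a group without counts were computed against a floor of 3 counts over the group and are lower bounds; floors cover counting error only.

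Genes were named by rule. For every contrast the 4 mutated demethylase genes and FLC were read. The 8 largest rises and the 8 largest falls were then taken among called genes whose groups did not overlap in CPM and whose higher group had a mean of at least 1 CPM. For the interaction the 5 largest in each direction were taken without the overlap condition. From each gene list up to 4 called members were added, lowest adjusted p first. Names, neighbours and gene order came from a RefSeq table of assembly TAIR10.1, which matched 37051 of the 37336 identifiers; the other 285 were organelle identifiers. No coordinates are printed, because the build of the counts is not known.

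The 26 gene lists held 385 genes, of which 322 passed the count filter. They covered the demethylases, the DNA methylation machinery, base excision repair, floral repressors and promoters, FLC regulators, imprinted genes, defence by salicylic acid, by jasmonate and ethylene and by immune receptors, responses to wounding, heat, and cold or drought, the clock, photosynthesis, senescence, flavonoid synthesis, the cell cycle, the stomatal lineage, markers of guard cells, phloem, xylem, trichomes and epidermis, the shoot meristem and floral organs, and reference genes. Annotated pseudogenes (187 measured) were added as a list. Transposable elements are not marked as a class in the reference and were not analysed here. Lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01 and again with an estimated correlation, adjusted over 156 tests; 38 passed with the preset correlation and 2 with the estimated one, those of the demethylase list in rdd and in drdd against WT. List means per library were compared between genotypes by exact permutation of the group labels.

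Alternatives were DESeq2's size factors in edgeR, no count filter, DESeq2 1.42.0, a fit of only the compared libraries, the replicate letter as a block, leaving out each library, a fold threshold, nuclear genes only, and leaving out genes near the mutated loci. For single named genes the first 6 of these were run. A fit without dme C and rdd B was added after the data were seen. No pair of replicates was a duplicate library: chi-square per degree of freedom over genes was 6.44 to 61.5 and the Pearson correlation of log2(CPM + 1) 0.935 to 0.989.

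Libraries held 8730340 to 23302135 gene counts, with 0.0185% to 0.0251% from organelle genes and 6.35% to 8.98% in the 10 most counted genes. The precision this gives was tested on simulated counts with the means, sizes and spread of these libraries. For dme against WT, 17.9% of genes changed 1.5-fold, 55.2% of those changed 2-fold and 87.9% of those changed 4-fold were called, among 18376 genes tested. For rdd against WT these shares were 11.9%, 49.3% and 87.9% (18370 genes), for drdd against WT 8.96%, 41.8% and 81.8% (18378 genes), for drdd against rdd 10.4%, 50.7% and 80.3% (18402 genes), for drdd against dme 4.48%, 40.3% and 77.3% (18385 genes), and for the interaction 0%, 16.4% and 68.2% (18399 genes). Unchanged genes called in these simulations numbered 2 to 5 per contrast. In a simulation of rdd against WT camera found the raised list and called 1 of 50 random lists at an unadjusted p under 0.05 (18379 genes), and the position test called 3 of 40 random sets of 200 genes. Genes were simulated as independent of each other. The simulation therefore cannot show how camera with the preset correlation behaves on lists of correlated genes. In these data the estimated correlation was 0.72 for the salicylic acid defence list in dme against WT.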

Results

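Polyadenylated RNA from the fifth rosette leaf of Arabidopsis thaliana was measured by RNA-seq in 15 libraries. The plants were 21 days old and had grown in long days with 16 h of light at 22 °C and 50% humidity. The libraries fall into 4 genotypes that differ in the DNA glycosylases DME, ROS1, DML2 and DML3, which excise methylated cytosine from DNA and so remove DNA methylation. WT are segregants in which all 4 genes are intact (4 libraries), dme carries the dme-2 allele (4 libraries), rdd carries ros1-3, dml2-1 and dml3-1 (4 libraries), and drdd carries all 4 mutant alleles (3 libraries). The labels name a transgene with DME under the AGL61 promoter for every genotype; this promoter is active in the central cell of the ovule, where DME is needed for seed survival. Libraries held between 8730340 counts (WT B) and 23302135 counts (rdd D) assigned to genes, with a median of 12178873. In all, 18598 genes passed the count filter. Expression levels are given as CPM (counts scaled to a common library size, with TMM factors), as mean ± SD with n = 4 libraries for WT, dme and rdd and n = 3 for drdd. Genes are named by their reference symbol, or by locus identifier where the reference has no symbol. The levels of near-identical copies (the RBCS, VSP, CBF and RLP genes, the MAF genes and the cytochrome P450 families) and of noncoding RNAs that overlap other genes are uncertain, because shared reads or reads of the opposite strand could be counted for either.

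The transcripts of the mutated genes were examined first. DML2 fell from 26.4 ± 4.41 CPM in WT to 6.96 ± 2.18 in rdd (log2 fold change −1.94, SE 0.21, adjusted p = 0.000141) and to 8.99 ± 2.29 in drdd (−1.54, SE 0.22, adjusted p = 0.00221), whereas dme stood at 26.6 ± 1.96. DML3 had 6.51 ± 1.39 CPM in WT, 7.07 ± 1.96 in dme, 3.23 ± 0.867 in rdd and 3.13 ± 0.626 in drdd, and passed the threshold in edgeR only between drdd and dme (log2 fold change −1.16, SE 0.28, adjusted p = 0.0470, lost under 14 of 20 single gene alternatives). The authors' deposited DESeq2 tables gave DML3 an adjusted p of 0.0147 for rdd and 0.0308 for drdd against WT. Single gene alternatives are other size factors, no filter, DESeq2, the compared libraries alone, the replicate block and each library left out. ROS1 was at 81.2 ± 10.9 CPM in WT, 89.1 ± 19.5 in dme, 58.5 ± 6.73 in rdd and 61.9 ± 4.82 in drdd, with an adjusted p of 0.161 for rdd against WT in edgeR and 0.0185 in the authors' deposited table. DME was at 89.5 ± 10.1 CPM in WT, 62.8 ± 8.40 in dme, 85.3 ± 14.4 in rdd and 73.9 ± 4.63 in drdd, with an adjusted p of 0.974 for dme against WT (log2 fold change −0.51, SE 0.13). Adjusted over the 4 mutated genes alone, 1 fell in dme against WT, and DME was the only one with a lower mean there. Counts were given per gene, so reads from either side of an insertion are included and these levels do not test whether a complete transcript was made. The DME levels can also include reads from the DME transgene that the labels name for every genotype.

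**Figure D1:**
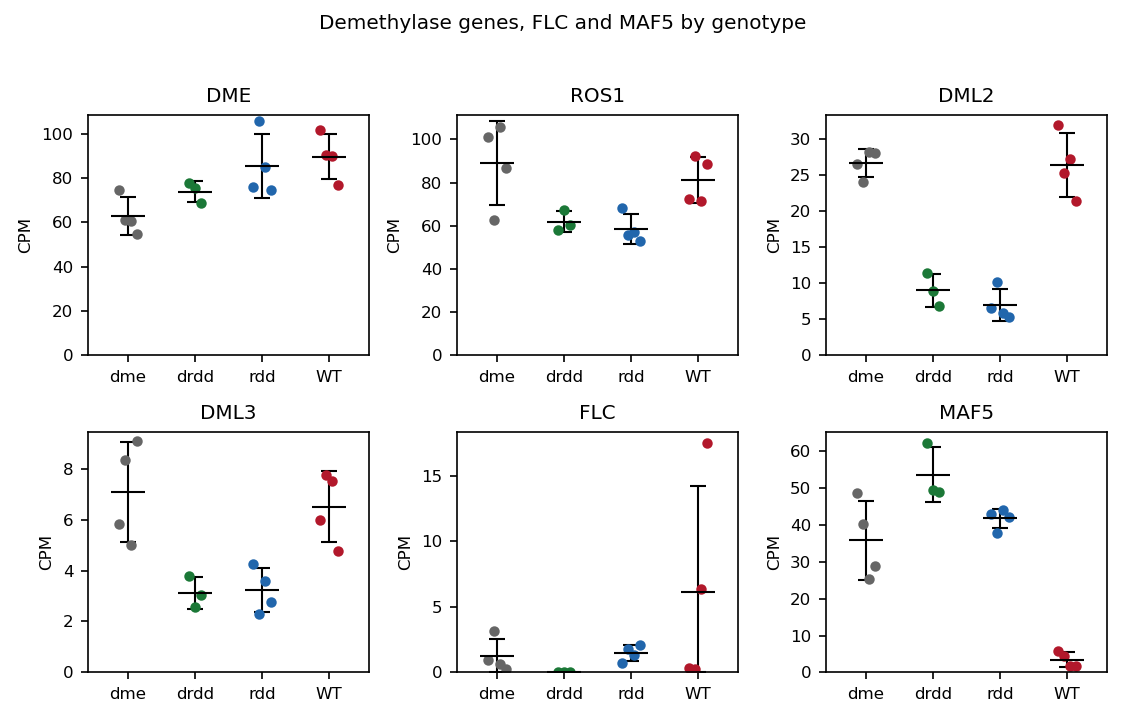
CPM of the 4 mutated demethylase genes and of the flowering repressors FLC and MAF5 in each library, by genotype (points are libraries, the long bar is the mean and the whiskers are the SD; n = 4, and n = 3 for drdd). DML2 lies below 12 CPM in every rdd and drdd library, and MAF5 lies above 25 CPM in every mutant library and below 6 CPM in every WT library.

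The title of the series names flowering time as an outcome, so the flowering repressor FLC, which lies within 2 Mb of DME, was read in every library. FLC varied most within WT, with 0.324 CPM in WT A, 0.228 in WT B, 6.36 in WT C and 17.5 in WT D. The dme libraries ranged from 0.253 to 3.19 CPM and the rdd libraries from 0.722 to 2.07 CPM. No FLC count was found in any of the 3 drdd libraries. With 3 counts over the group as the floor, the drdd level was at least 80.9-fold lower than the WT mean, at least 16.8-fold lower than the dme mean and at least 19.5-fold lower than the rdd mean. These limits rest on single libraries: they were 41.3-fold, 8.59-fold and 9.98-fold without drdd B, 30.6-fold against WT without WT D, and 8.31-fold against dme without dme B. None of these differences passed the threshold in edgeR (adjusted p = 0.103 against WT, 0.214 against dme and 0.298 against rdd). DESeq2 gave adjusted p = 1.34e-05, 0.00352 and 0.00551. The authors' deposited DESeq2 tables gave an adjusted p of 0.00913 against WT and 0.000145 against rdd. Over the alternatives tried the adjusted p against WT ranged up to 0.294, against dme up to 0.419 and against rdd up to 0.560.

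Loss of DME alone was compared with WT first. MAF5, a MADS-box gene of the FLC clade that represses flowering, rose from 3.43 ± 2.01 CPM in WT to 35.8 ± 10.7 CPM in dme (log2 fold change 3.39, SE 0.33, adjusted p = 0.00163). SAT32, named after salt tolerance, fell from 57.4 ± 4.64 to 27.8 ± 4.23 CPM (log2 fold change −1.05, SE 0.12, adjusted p = 0.00398). These were the 2 genes past the threshold, with 1 higher and 1 lower. The other 19 of the 20 measured floral repressors did not pass, and adjusted over the list alone 1 rose and 1 fell.

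Several stress lists stood apart from other genes in dme, although no member passed the threshold over all genes tested. The rapid wound and touch list, whose 12 measured members include transcription factors of the ZAT, ERF and CBF families, had a median log2 fold change of 1.89, with a camera adjusted p of 0.000149 and an adjusted p of 0.824 with an estimated correlation. The library means of this list were 3.37, 4.02, 6.83 and 3.04 log2 CPM in dme A to D, against 3.98, 2.66, 3.31 and 3.04 in WT A to D. The 25 measured jasmonate and ethylene defence genes had a median of 0.25 (adjusted p = 0.000187, and 0.977 with an estimated correlation), with library means of 4.88, 1.79, 3.57 and 1.73 log2 CPM in WT A to D and 2.79 to 4.76 in dme. The 26 NLR and pattern receptor genes had a median of 0.10 (adjusted p = 0.0234, and 0.977 with an estimated correlation), with library means of 5.24 to 5.84 log2 CPM in dme and 4.94 to 5.89 in WT. For the 29 salicylic acid defence genes the median was 0.12 and the mean −0.05 (camera direction up, adjusted p = 0.00860, and 0.977 with an estimated correlation), and the library means of this list spread from 2.90 to 5.65 log2 CPM within WT. The 11 abscisic acid, cold and drought genes had a median of −0.80 (adjusted p = 0.0108, and 0.977 with an estimated correlation). The library means of this list were 4.22, 5.95, 4.11 and 6.19 log2 CPM in WT A to D and 4.35 to 4.81 in dme, so that every dme library lay above WT A and WT C and below WT B and WT D. In each of these 5 lists 0 members passed when adjusted over the list alone.

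Across the 18598 genes, edgeR's quasi-likelihood test gave 841 genes at an unadjusted p under 0.05 for dme against WT. That is a smaller share than the 0.05 that tests without any difference would give. The authors' deposited table gave 2 higher and 7 lower genes at an adjusted p under 0.05, which include both genes named here. With only the WT and dme libraries in the fit neither gene passed (adjusted p = 0.278 for both).

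The loss of ROS1, DML2 and DML3 together was then compared with WT. MAF5 was again higher, at 41.7 ± 2.67 CPM in rdd (log2 fold change 3.61, SE 0.34, adjusted p = 5.35e-05). AT2G32160 fell from 85.5 ± 43.0 to 0.294 ± 0.288 CPM (log2 fold change −8.22, SE 0.56), RLP34, a receptor-like protein gene, from 98.9 ± 84.3 to 0.472 ± 0.494 CPM (−7.90, SE 0.94), and the long noncoding RNA AT2G24755 from 17.8 ± 1.90 to 0.0697 ± 0.0472 CPM (−7.76, SE 0.32). In all, 77 genes were higher and 123 lower in rdd than in WT.

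Among the other large falls, MRD1 went from 10.5 ± 11.7 to 0.0893 ± 0.128 CPM. AT3G09162 and the noncoding RNAs AT4G04223 and AT2G22821, together with AT2G25150, had no count in any rdd library and 2.43 ± 0.748, 1.83 ± 1.05, 1.52 ± 0.708 and 1.79 ± 1.01 CPM in WT. Against the floor of 3 counts over the group these were at least 44.8-fold, 33.7-fold, 27.9-fold and 32.9-fold lower in rdd, in that order, and without rdd D at least 26.0-fold, 19.5-fold, 16.2-fold and 19.1-fold. The largest rises started from levels at or near zero in WT. The noncoding RNA AT3G06245 had no count in WT and 2.36 ± 0.728 CPM in rdd, which is at least 35.7-fold higher. AT2G21045 had no count in WT and 1.53 ± 0.562 CPM in rdd, at least 23.1-fold higher. The cytochrome P450 genes CYP705A9, CYP72A10 and CYP81D11 rose to 3.37 ± 0.602, 2.50 ± 0.496 and 3.18 ± 2.29 CPM (log2 fold changes 5.97, 5.03 and 4.98). AT3G07260 rose to 3.09 ± 0.665 CPM, AT3G01270 to 1.12 ± 0.827 CPM, and VGD1, a pectin methylesterase gene of pollen tubes, to 1.35 ± 0.857 CPM.

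The stomatal lineage list, which covers early genes and the late gene FAMA, stood higher in rdd by camera with the preset correlation (adjusted p = 1.18e-05) but not with an estimated one (0.650). The 10 measured members had a median log2 fold change of 1.73; none passed in edgeR over all genes tested and 4 rose adjusted over the list alone. These were SPCH, which starts the lineage (0.222 ± 0.140 CPM in WT, 2.33 ± 0.854 in rdd), the receptor-like gene TMM (1.61 ± 1.14 and 9.76 ± 3.68 CPM), and the cell polarity genes POLAR (0.255 ± 0.195 and 1.49 ± 0.452 CPM) and BASL (0.344 ± 0.372 and 1.46 ± 0.815 CPM). In the authors' deposited table TMM, SPCH and POLAR passed (adjusted p = 5.81e-05, 3.73e-05 and 0.00944) and BASL did not (0.154). Among markers of other leaf cell types, the 7 guard cell markers had a median of 0.36 (3 rose adjusted over the list alone, adjusted p = 0.0126, and 0.824 with an estimated correlation) and the 6 xylem markers a median of 0.83 (2 rose adjusted over the list alone, adjusted p = 0.00193, and 0.824 with an estimated correlation).

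The lists of immune receptors and of salicylic acid defence had lower values in rdd on the camera test. The jasmonate and ethylene defence list did not pass (median −0.72, camera adjusted p = 0.203). The 26 NLR and pattern receptor genes had a median of −0.31 (1 fell adjusted over the list alone, adjusted p = 0.00230, and 0.977 with an estimated correlation). Their library means were 5.89, 4.94, 5.38 and 5.01 log2 CPM in WT A to D and 4.98, 5.35, 4.74 and 4.71 in rdd A to D, so that WT A and WT C stood apart from WT B and WT D here as well. The 29 salicylic acid defence genes had a median of −0.33 (0 passed adjusted over the list alone, adjusted p = 0.0202, and 0.977 with an estimated correlation). The library means of the salicylic acid list were 2.88, 5.45, 2.50 and 2.49 log2 CPM in rdd A to D and 5.65, 2.90, 4.94 and 3.05 in WT A to D, so that rdd B stood with WT A and WT C. The list of the 4 mutated demethylase genes was lower (1 fell, 3 adjusted over the list alone, adjusted p = 7.63e-06), and held with an estimated correlation (adjusted p = 0.0460).

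Called genes of rdd against WT were spread unevenly over the chromosomes. Chromosome 2, which carries ROS1, held 79 calls among 2807 tested genes (2.81%), and chromosome 3, which carries DML2, held 61 among 3692 (1.65%). Chromosome 4, which carries DML3, held 21 calls (0.737%), and chromosomes 1 and 5 held 17 and 22 (0.348% and 0.510%). Within 2 Mb of ROS1, DML2 or DML3 lay 64 of the 200 calls (32.0%, against 13.6% of the tested genes). Of these, 24 lay near ROS1 (809 tested genes), 37 near DML2 (886) and 3 near DML3 (832). Within 2 Mb of any of the 4 mutated genes lie 17.5% of the tested genes. Of the 59 genes named by the rule for any comparison, other than the mutated genes, 14 lie there. They are AT2G32160, AGO6, AT2G33830, AT2G34655, RCA and EXPA8 near ROS1, AT3G07260, AT3G09160, AT3G09162, RLP34 and CYP72A10 near DML2, POLAR near DML3, and PRR7 and FLC near DME. The window does not show that named genes outside it are unlinked to a mutated gene.

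**Figure D2:**
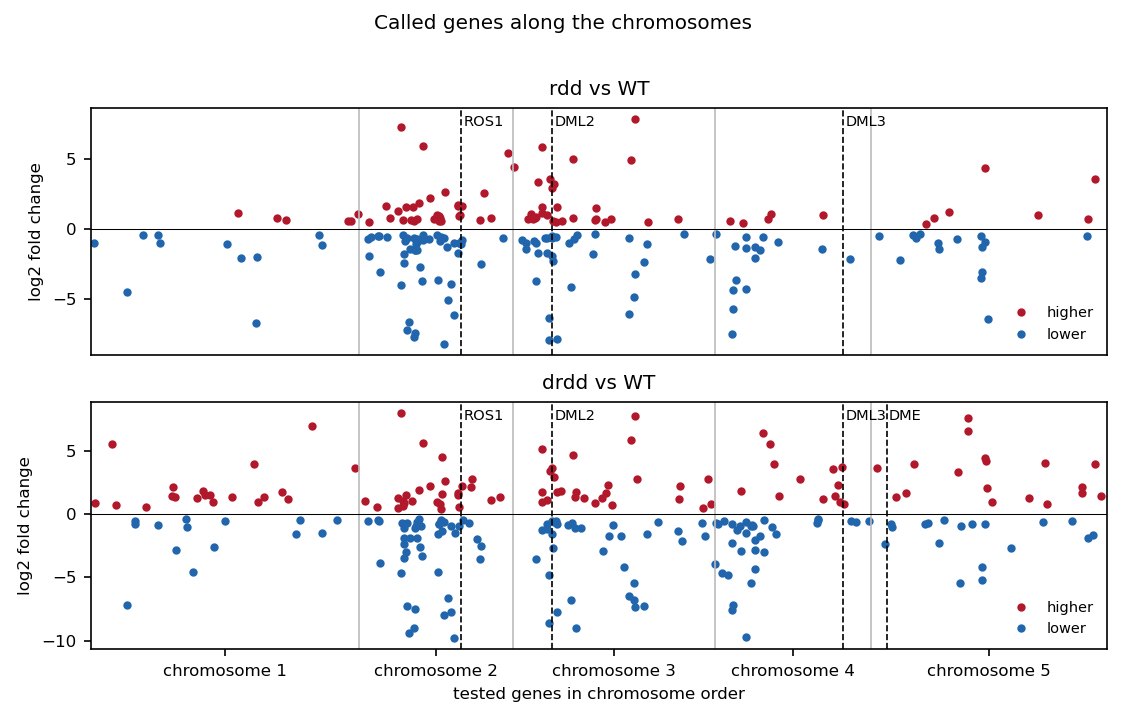
Log2 fold change of each gene past the threshold in rdd against WT (top) and drdd against WT (bottom), placed by its rank among the tested genes in chromosome order. Red points are higher and blue points lower in the mutant, dashed lines mark the mutated genes, and grey lines separate the chromosomes; chromosome 2 holds 79 of the rdd calls and 73 of the drdd calls.

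The authors' deposited table gave 496 higher and 447 lower genes for rdd against WT, and 199 of the 200 edgeR calls were among them in the same direction. Leaving out single libraries moved the count of 200 by more than 1.5 times: it was 110 without WT A, 94 without WT C, 113 without rdd A, 100 without rdd C and 93 without rdd D. It was 315 without dme C, 327 without rdd B and 504 without both, an alternative chosen after the data were seen. Among the named genes, AT3G06245, CYP705A9, AT3G07260, CYP72A10, AT2G32160, AT3G09162, RLP34, AT2G24755, DML2 and MAF5 passed under every single gene alternative, and the other called ones were lost under at least 1.

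With all 4 demethylases mutated, drdd differed from WT in 251 genes, 104 higher and 147 lower. MAF5 rose to 53.5 ± 7.47 CPM (log2 fold change 3.97, SE 0.35, adjusted p = 2.47e-05). Among the largest rises, the vegetative storage protein genes VSP1 and VSP2 went from 0.119 ± 0.137 and 0.183 ± 0.268 CPM in WT to 22.9 ± 24.5 and 19.6 ± 20.6 CPM in drdd, and the beta-amylase gene BAM5 went from 0.760 ± 0.487 to 63.1 ± 63.7 CPM. PERK13, a receptor-like kinase gene known from root hairs, rose from 0.180 ± 0.0320 to 22.3 ± 14.1 CPM (log2 fold change 6.90, SE 0.77, adjusted p = 0.000217).

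CYP81D11 (5.58 ± 6.77 CPM) and CYP705A9 (2.59 ± 0.657 CPM) were higher in drdd as well, as were AT2G21045 at 2.43 ± 0.745 CPM, at least 36.8-fold above WT, and AT3G06245 at 2.08 ± 1.07 CPM, at least 31.4-fold above WT. Of the largest falls, AT2G32160 and RLP34 reached 0.379 ± 0.218 and 0.465 ± 0.299 CPM, and AT2G24755 reached 0.0171 ± 0.0296 CPM (log2 fold change −9.00, SE 0.41). The genes AT2G34655, AT4G11000 and AT3G09160 and the annotated pseudogenes AT2G23330 and AT3G15310 had no count in any drdd library. Their WT levels were 8.54 ± 8.56, 8.28 ± 5.00, 3.88 ± 0.590, 6.66 ± 0.567 and 4.87 ± 4.14 CPM, which puts drdd at least 113-fold, 110-fold, 51.6-fold, 88.4-fold and 64.6-fold lower. Without drdd B these limits were 57.9-fold, 56.2-fold, 26.3-fold, 45.2-fold and 33.0-fold; that of AT2G34655 was 65.4-fold without WT A and that of AT3G15310 37.5-fold without WT C. The calls of AT2G34655 and AT3G15310 were lost under 9 and 15 of 20 single gene alternatives. Of the 187 measured pseudogenes, 1 rose and 8 fell, and adjusted over the list alone 1 rose and 10 fell (median −0.13, camera adjusted p = 0.0212, and 0.650 with an estimated correlation). In rdd against WT 1 rose and 8 fell as well, and adjusted over the list alone 3 rose and 12 fell (median −0.07, camera adjusted p = 0.133).

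The stomatal lineage list showed 3 rises and 1 fall among its 10 measured members in drdd. TMM rose from 1.61 ± 1.14 to 20.4 ± 8.79 CPM (log2 fold change 3.64, SE 0.61, adjusted p = 0.00879), POLAR from 0.255 ± 0.195 to 3.26 ± 1.70 CPM and SPCH from 0.222 ± 0.140 to 3.80 ± 2.13 CPM. FAMA, which acts late in the lineage when guard cells form, fell from 34.8 ± 5.22 to 18.7 ± 5.74 CPM (log2 fold change −0.89, SE 0.19, adjusted p = 0.0306). Adjusted over the list alone 6 rose and 1 fell (camera adjusted p = 4.18e-06, and 0.650 with an estimated correlation). The 21 cell cycle genes had a median of 0.51 (0 passed adjusted over the list alone, adjusted p = 5.51e-05, and 0.824 with an estimated correlation), and the 6 xylem markers a median of 1.00 (4 rose adjusted over the list alone, adjusted p = 0.00196, and 0.824 with an estimated correlation).

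**Figure D3:**
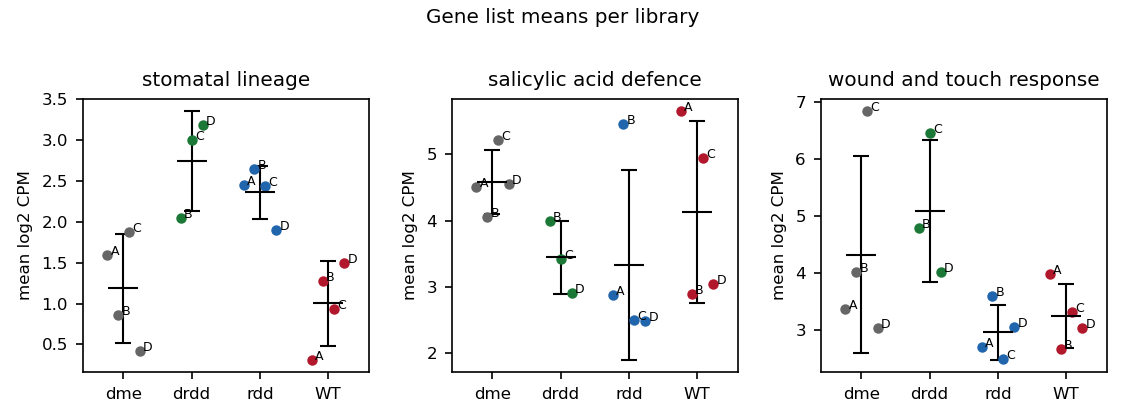
Mean log2 CPM of the stomatal lineage (10 genes), salicylic acid defence (29 genes) and rapid wound and touch (12 genes) lists in each library, by genotype (points are libraries with their replicate letter, the long bar is the mean and the whiskers are the SD; n = 4, and n = 3 for drdd). The stomatal lineage means are 1.00 in WT, 1.19 in dme, 2.36 in rdd and 2.74 in drdd, while the salicylic acid list spreads from 2.49 to 5.45 within rdd.

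Stress lists stood higher in drdd than in WT with wide spread between libraries. Of the 25 jasmonate and ethylene defence genes, VSP1 and VSP2 rose, 23 did not pass, and the median was 0.65 (2 rose adjusted over the list alone, adjusted p = 0.00149, and 0.977 with an estimated correlation), with library means of 2.62 to 4.91 log2 CPM in drdd and 1.73 to 4.88 in WT. The wound and touch list had a median of 2.42 (0 passed adjusted over the list alone, adjusted p = 0.000153, and 0.824 with an estimated correlation), with library means of 4.79, 6.45 and 4.02 log2 CPM in drdd B to D. Of the 11 abscisic acid, cold and drought genes 1 rose, the dehydrin gene RAB18, from 17.5 ± 8.22 to 47.5 ± 18.4 CPM (adjusted p = 0.0355, lost under 10 of 20 single gene alternatives; list median 0.78, library means 5.67, 7.14 and 5.30 log2 CPM in drdd B to D, 1 rose adjusted over the list alone, camera adjusted p = 0.00420, and 0.977 with an estimated correlation). Of the 17 clock genes, ELF3 fell from 105 ± 4.74 to 81.5 ± 1.47 CPM (log2 fold change −0.37, SE 0.08, adjusted p = 0.0344), a call lost under 14 of 20 single gene alternatives. The NLR and pattern receptor list had a median of −0.27 (0 passed adjusted over the list alone, adjusted p = 0.00158, and 0.977 with an estimated correlation), with library means of 4.87 to 5.10 log2 CPM in drdd, near those of WT B and WT D. The demethylase list was lower (1 fell, 3 adjusted over the list alone, adjusted p = 5.51e-05, and 0.0468 with an estimated correlation).

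The authors' deposited table gave 362 higher and 328 lower genes for drdd against WT, and 245 of the 251 edgeR calls were among them in the same direction. The count of 251 was 125 without WT C, 119 without drdd B, 105 without drdd C and 111 with only the WT and drdd libraries in the fit. Of the named genes DML2, MAF5, PERK13, CYP705A9, AT4G11000, AT2G23330, AT2G24755, AT3G09160, AT2G32160 and TMM passed under every single gene alternative, and the other called ones were lost under at least 1.

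**Figure D4:**
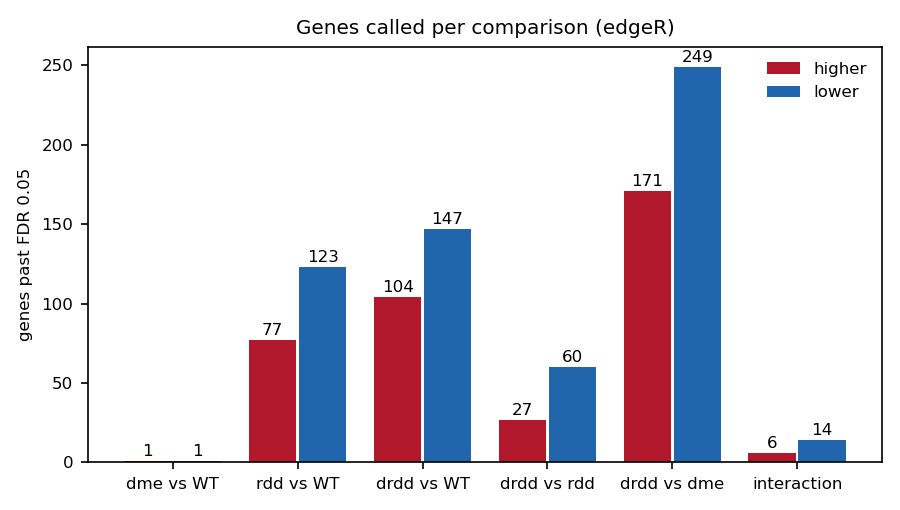
Number of genes higher (red) and lower (blue) at an adjusted p under 0.05 in edgeR for each comparison, out of 18598 tested. The bars run from 1 higher and 1 lower for dme against WT to 171 higher and 249 lower for drdd against dme.

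The calls of rdd and drdd against the same WT libraries overlapped. They shared 31 higher and 57 lower genes, against 0.431 and 0.972 for independent lists of these sizes, and 1 gene was called in opposite directions. The correlation of the log2 fold changes across genes, which are not independent replicates, was 0.691, and 0.469 in 20 simulations of unchanged groups against the same WT libraries. Their covariance was 0.315 against a simulated 0.0692, a difference of 0.246. Genes were simulated as independent of each other, so the simulations leave out variation that many genes share between libraries. The difference is therefore not a measure of significance. When the 4 WT libraries were divided between the comparisons, 32 to 57 calls were shared over the 6 divisions, with a covariance of 0.0657 to 0.320. The dme comparison shared 1 call, MAF5, with each of the others; its covariance with rdd was 0.0639 (simulated 0.0690) and with drdd 0.109 (simulated 0.0687).

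The effect of DME where the other 3 demethylases were already mutated was read from drdd against rdd. CYP706A6, a cytochrome P450 gene, fell from 192 ± 32.2 CPM in rdd to 3.88 ± 1.08 CPM in drdd (log2 fold change −5.64, SE 0.29, adjusted p = 1.33e-07), and AT5G22860 fell from 9.75 ± 2.42 to 0.348 ± 0.305 CPM (−4.84, SE 0.43, adjusted p = 7.02e-05). The expansin gene EXPA8 fell from 54.9 ± 16.6 to 4.797 ± 2.65 CPM, the arabinogalactan protein gene AGP2 from 8.22 ± 1.02 to 0.441 ± 0.510 CPM, and AT2G33830, a dormancy-associated gene, from 10.6 ± 2.47 to 0.809 ± 0.316 CPM. PERK13 rose from 0.274 ± 0.256 to 22.3 ± 14.1 CPM (log2 fold change 6.49, SE 0.74, adjusted p = 0.000856). In all, 27 genes were higher and 60 lower in drdd than in rdd. Chromosome 4, which carries DML3, held 27 of these calls among 2849 tested genes (0.948%). The other chromosomes held 14 to 16 calls each (0.307% to 0.534%), and 3 calls lay within 2 Mb of DME on chromosome 5. The cause of this uneven spread was not tested, so these differences are not shown to follow from DME loss itself.

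Further rises included JMT, which makes methyl jasmonate (3.16 ± 1.35 to 14.4 ± 6.50 CPM), VSP2 (0.478 ± 0.585 to 19.6 ± 20.6 CPM), BAM5 (2.72 ± 1.82 to 63.1 ± 63.7 CPM), the mannan synthase gene CSLA01 (0.145 ± 0.162 to 4.33 ± 4.44 CPM), and the nucleoside transporter gene ENT6 (0.262 ± 0.0702 to 5.59 ± 1.63 CPM). The receptor-like kinase gene CRK40 rose from 7.73 ± 2.67 to 52.3 ± 20.5 CPM, with 155 ± 81.2 CPM in WT. AT3G46370, AT4G00070 and the annotated pseudogene AT4G01490 fell to 0.0328 ± 0.0568, 0.0670 ± 0.0581 and 0.378 ± 0.319 CPM. Of the 15 measured floral promoters, SOC1, a flowering integrator, rose from 40.9 ± 4.102 to 73.6 ± 3.86 CPM (log2 fold change 0.85, SE 0.17, adjusted p = 0.0416). The other 14 did not pass, 1 rose adjusted over the list alone, and the list had a median of 0.56 (camera adjusted p = 0.00193, and 0.109 with an estimated correlation). FT, which encodes the mobile flowering signal, had a log2 fold change of 1.52 (SE 0.70, adjusted p = 0.434).

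The jasmonate and ethylene defence list had a median of 1.46 in drdd against rdd (1 rose, 7 adjusted over the list alone, camera adjusted p = 2.54e-09, and 0.824 with an estimated correlation). Its library means were 4.38, 4.91 and 2.62 log2 CPM in drdd B to D and 1.94 to 3.05 in rdd, so that drdd D lay within the range of rdd. In the wound and touch list CBF3, a cold-response transcription factor, rose from 2.18 ± 0.597 to 16.9 ± 8.90 CPM. Of the list 7 rose adjusted over the list alone, and the median was 2.81 (adjusted p = 8.65e-08, and 0.673 with an estimated correlation). The library means of that list were 2.69, 3.59, 2.49 and 3.05 log2 CPM in rdd A to D. The abscisic acid, cold and drought list had a median of 1.22 (1 rose adjusted over the list alone, adjusted p = 0.00193, and 0.877 with an estimated correlation) and the cell cycle list a median of 0.29 (0 passed adjusted over the list alone, adjusted p = 0.0343, and 0.977 with an estimated correlation). FAMA fell from 40.7 ± 4.101 to 18.7 ± 5.74 CPM and the other 9 stomatal lineage genes did not pass, while the guard cell markers had a median of −0.34 (1 fell adjusted over the list alone, adjusted p = 0.00247, and 0.673 with an estimated correlation).

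All 87 calls were in the authors' deposited table in the same direction, which gave 324 higher and 281 lower genes for this comparison. The count of 87 was 53 without WT B, 50 without WT C, 51 without dme A, 52 without dme B, 34 without rdd A, 25 without rdd C, 32 without rdd D, 33 without drdd B and 19 without drdd C. It was 50 with only the rdd and drdd libraries in the fit and 134 without dme C and rdd B. Of the named genes PERK13, ENT6, CYP706A6, AT5G22860, AGP2, AT2G33830, AT4G01490 and EXPA8 passed under every single gene alternative, and the adjusted p of SOC1 ranged from 0.000815 to 0.201.

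The loss of ROS1, DML2 and DML3 where DME was already mutated was examined in drdd against dme, for which no authors' table was used here. Sequence linked to these alleles could differ in the same comparison, so its calls are not shown to follow from demethylase loss itself. Here 171 genes were higher and 249 lower in drdd. Of the photosynthesis list the Rubisco small subunit genes RBCS2B and RBCS1B fell from 6523 ± 676 and 3348 ± 542 CPM to 3084 ± 887 and 1948 ± 320 CPM, and the Rubisco activase gene RCA from 9908 ± 1873 to 5265 ± 1770 CPM. The clock genes GI and PRR7 rose from 8.07 ± 1.72 and 14.6 ± 3.98 CPM to 28.0 ± 18.3 and 40.1 ± 24.8 CPM, and ELF3 fell from 107 ± 7.28 to 81.5 ± 1.47 CPM.

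Of the 28 photosynthesis genes 3 fell and 25 did not pass; adjusted over the list alone 4 rose and 5 fell (median 0.08, camera direction down, adjusted p = 0.976). In the stomatal lineage list POLAR, TMM and BASL rose (BASL from 0.311 ± 0.235 to 3.35 ± 1.70 CPM, adjusted p = 0.0459) and FAMA fell. Adjusted over the list alone 6 rose and 1 fell (adjusted p = 0.000102, and 0.797 with an estimated correlation). RAB18 rose from 14.2 ± 1.48 to 47.5 ± 18.4 CPM (log2 fold change 1.74, SE 0.31, adjusted p = 0.0111), with 5 of the 11 abscisic acid, cold and drought genes higher adjusted over the list alone (camera adjusted p = 1.76e-05, and 0.824 with an estimated correlation). AGO6, a component of RNA-directed DNA methylation, rose from 1.80 ± 0.235 to 4.35 ± 1.29 CPM (adjusted p = 0.0484), and the other 29 of 30 measured genes of that machinery did not pass. The floral promoter list had GI as its rise, 2 rises adjusted over the list alone and a median of 0.31 (adjusted p = 0.0260, and 0.409 with an estimated correlation). The salicylic acid defence list had a median of −0.99 (0 passed adjusted over the list alone, adjusted p = 0.000173, and 0.977 with an estimated correlation). Its library means were 4.51, 4.05, 5.21 and 4.55 log2 CPM in dme A to D and 4.003, 3.43 and 2.91 in drdd B to D. The NLR and pattern receptor list had a median of −0.46 (1 fell adjusted over the list alone, adjusted p = 9.74e-06, and 0.877 with an estimated correlation). The cell cycle list had a median of 0.43 (0 passed adjusted over the list alone, adjusted p = 0.00191, and 0.977 with an estimated correlation) and the xylem markers a median of 0.95 (3 rose adjusted over the list alone, adjusted p = 0.00709, and 0.848 with an estimated correlation). Of the demethylase list DML2 and DML3 fell, 3 adjusted over the list alone (adjusted p = 0.00149, and 0.109 with an estimated correlation).

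PERK13, CSLA01, CYP705A9, BAM5, VSP1 and VSP2 were among the rises from dme to drdd, as were CBF3 (3.45 ± 1.26 to 16.9 ± 8.90 CPM), AT3G06245, AT3G07260 and AT2G21045, which had no count in dme and was at least 40.2-fold higher in drdd. The falls included AT2G32160 (118 ± 34.5 to 0.379 ± 0.218 CPM) and AT2G24755, and AT4G11000, AT2G23330, AT3G09160, AT2G34655, AT1G57850 and AT2G22821 had no count in drdd. The drdd level of these 6 was at least 143-fold, 91.0-fold, 62.6-fold, 53.0-fold, 50.8-fold and 23.9-fold below the dme mean, and without drdd B at least 73.2-fold, 46.5-fold, 32.0-fold, 27.1-fold, 25.9-fold and 12.2-fold. The count of 420 was 188 without dme B, 222 without dme D, 156 without drdd B, 126 without drdd C and 134 with only the dme and drdd libraries in the fit. Among the named genes DML2, AT2G21045, PERK13, CYP705A9, AT3G06245, AT3G07260, AT4G11000, AT2G23330, AT2G24755, AT3G09160 and AT2G32160 passed under every single gene alternative; the other called ones, among them RBCS2B, RBCS1B, RCA, GI, PRR7 and ELF3, were lost under at least 1.

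Whether the difference between drdd and rdd departed from that between dme and WT was tested as an interaction, which gave 6 positive and 14 negative genes. The cause was not tested, and a trait of a single line would also give an interaction. These calls are therefore not shown to follow from DME loss itself. Chromosome 4 held 6 of these calls and each other chromosome 2 to 4. CYP706A6 had 166 ± 40.1 CPM in WT, 177 ± 33.9 in dme, 192 ± 32.2 in rdd and 3.88 ± 1.08 in drdd (interaction log2 fold change −5.73, SE 0.33, adjusted p = 9.57e-07). AT5G22860 had 14.5 ± 3.16, 14.1 ± 3.34, 9.75 ± 2.42 and 0.348 ± 0.305 CPM in the same order (−4.80, SE 0.51), and AGP2 4.03 ± 0.374, 5.07 ± 2.14, 8.22 ± 1.02 and 0.441 ± 0.510 CPM (−4.32, SE 0.62). AT2G33830 stood at 162 ± 41.7, 119 ± 26.5, 10.6 ± 2.47 and 0.809 ± 0.316 CPM (−3.35, SE 0.41). MAF5 had a negative interaction (−3.03, SE 0.45, adjusted p = 0.0192): its log2 fold change was 3.39 from WT to dme and 0.36 (SE 0.31) from rdd to drdd.

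**Figure D5:**
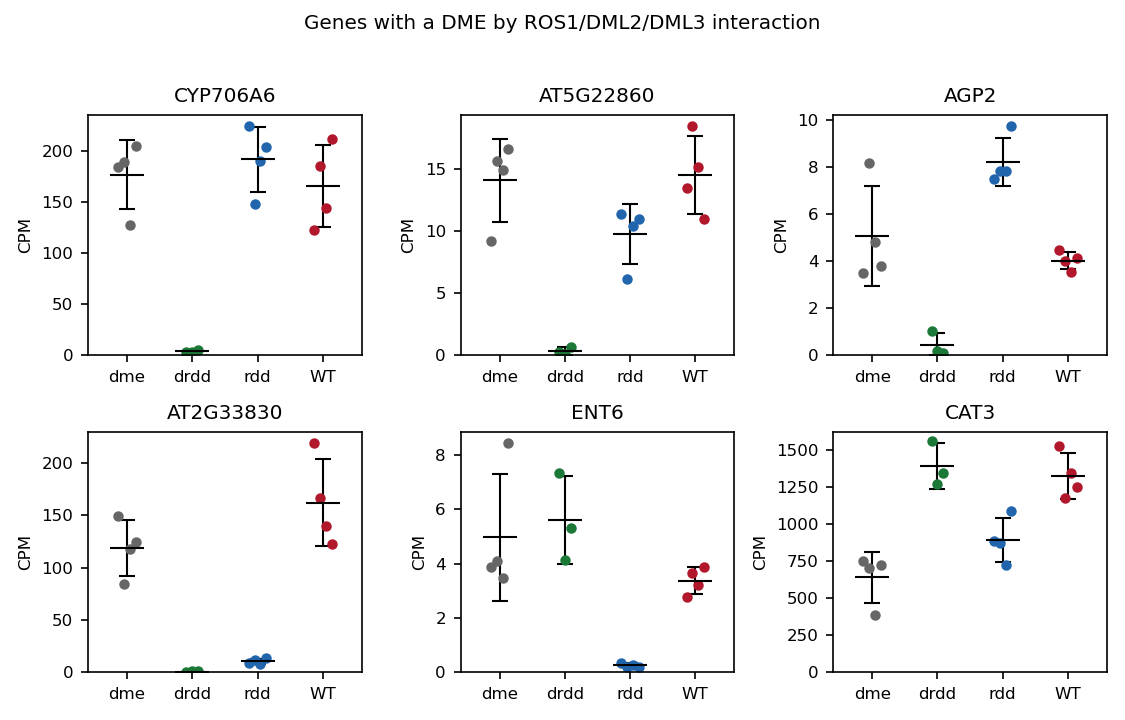
CPM of 6 genes past the threshold of the interaction test in each library, by genotype (points are libraries, the long bar is the mean and the whiskers are the SD; n = 4, and n = 3 for drdd). CYP706A6, AT5G22860 and AGP2 are lowest in drdd, ENT6 is lowest in rdd, and CAT3 is lowest in dme.

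Positive interactions were found for ENT6 (3.37 ± 0.492 CPM in WT, 4.96 ± 2.32 in dme, 0.262 ± 0.0702 in rdd and 5.59 ± 1.63 in drdd; log2 fold change 3.84, SE 0.48) and for CAT3, a catalase gene (1324 ± 152, 640 ± 171, 892 ± 149 and 1391 ± 152 CPM; 1.69, SE 0.28, adjusted p = 0.0258). SAT32, AT1G06640 and AOC4, an allene oxide cyclase gene of jasmonate synthesis, had interactions of 1.15, 1.03 and 0.96, and the pseudogene AT4G01490 of −3.92. By camera the abscisic acid, cold and drought list (median 1.69, 3 positive adjusted over the list alone, adjusted p = 5.51e-05, and 0.824 with an estimated correlation), the floral promoters (median 0.42, adjusted p = 0.00417, and 0.147 with an estimated correlation) and the jasmonate and ethylene defence list (median 0.80, adjusted p = 0.0116, and 0.977 with an estimated correlation) were positive. The guard cell markers were negative (median −0.49, adjusted p = 0.0343, and 0.824 with an estimated correlation).

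The count of 20 was 13 without WT B, 13 without WT C, 8 without dme B, 9 without rdd A, 7 without rdd C, 6 without drdd C and 45 without drdd D. CYP706A6, AT5G22860, AT2G33830 and ENT6 passed under every single gene alternative.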

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

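The position test at each window, the interaction contrast and the exact permutation of group labels on the salicylic acid list were chosen before their results were seen. What the position test says of linked sequence and what the interaction says of MAF5 were set down after. Every other test of an explanation in this part was chosen after the result was seen.

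Calls of rdd against WT were more frequent near the mutated genes as a set, with 64 of 200 within 2 Mb of ROS1, DML2 or DML3 (32.0%, against 13.6% of tested genes), but this held for DML2 (37 of 886 tested genes) and ROS1 (24 of 809, much as over all of chromosome 2 with 79 of 2807) and not for DML3 (3 of 832). Reads of another accession lost in alignment would have left nearly all of these calls lower in rdd, but 46.9% were higher, which argues against that as the whole cause. Sequence linked to the insertion alleles may contribute, since the share near the loci was larger than after rotating the calls along the genome (one-sided permutation of positions by circular shifts, p = 0.0321 at 2 Mb, but 0.0572 at 1 Mb and 0.0833 at 5 Mb), while for drdd against WT (70 of 251 calls, p = 0.0718) and drdd against dme (83 of 420 calls, p = 0.0766) it cannot be told apart from chance at 2 Mb and passed at 1 Mb (permutation p = 0.0310 and 0.00480). For the 39 rdd calls on chromosomes 1 and 5, which carry none of the genes mutated in rdd, differences of the WT libraries alone are argued against as the whole cause. In drdd against dme, a comparison with other libraries, the mean log2 difference of these genes in the direction seen in rdd was 0.914. The other of the 35 divisions of those libraries gave at most 0.467. Each of them puts dme and drdd libraries in 1 group, which lowers its value by construction. Only the rank of 1 in 35 therefore counts, the smallest share that these divisions can give. The share of the same sign, 74.4%, was as high in 7 of the 35, so differences of the WT libraries stay open as a part. Loss of demethylation near these loci is a biological explanation that the genotypes allow, and it was not tested.

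MAF5 was higher in all 3 mutants, at 35.8 CPM in dme, 41.7 in rdd and 53.5 in drdd against 3.43 in WT. Reads moved from the neighbouring MAF2, MAF3 and MAF4 are argued against as the whole cause, because the summed level of these 3 genes fell in no mutant. The lowest change of this sum was a gain of 0.826% of what MAF5 gained. MAF4 itself stood at 4.36, 8.40, 11.9 and 7.93 CPM in WT, dme, rdd and drdd. Reads that align to several of these genes may be missing from the counts, so a shift of such reads was not measurable. Separate effects of DME and of the other 3 demethylases that multiply are argued against by the interaction (log2 fold change −3.03, adjusted p = 0.0192 in edgeR), while effects that add in CPM stay open: drdd differed by −20.6 CPM (SE 7.06) from the 74.1 CPM that adding gives, but the interaction lay 0.476 from the −2.56 that adding gives, about its SE of 0.45. A sequence difference of the WT line around MAF5 may still be the source: 0 of the 20 nearest tested genes passed in edgeR (lowest adjusted p = 0.0742, with 6 at an unadjusted p under 0.05 in at least 1 comparison, and 1, ASN2, past 0.05 in the authors' deposited tables), but a difference at MAF5 alone would leave its neighbours as they are. Loss of demethylation at MAF5 itself stays open, untested.

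The salicylic acid defence list differed widely within genotypes, with library means of 5.65, 2.90, 4.94 and 3.05 log2 CPM in WT A to D and with rdd B at 5.45 against 2.49 to 2.88 in the other rdd libraries, a gap of 0.867 of the group's range. A batch shared by replicate letters is argued against as the whole cause: the mean product of same-letter deviations was −0.110, where that cause needs about the variance within groups of 1.19 (exact permutation of letters p = 0.640). Genotype is the same within a group and so was not weighed for this spread; between groups the list means gave an exact permutation p of 0.3725, with 23.5% of the variance. Differences between single plants, such as infection, may also play a part and were not tested.

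The other single libraries far from their group stand here as values. CYP81D11 was at 1.78 CPM in dme C and 0.337 to 0.490 in the other dme libraries (gap 0.894 of the range), and at 6.59 in rdd A and 1.81 to 2.40 in the other rdd libraries (gap 0.876). VSP2 was at 1.35 CPM in rdd A and 0.172 to 0.209 in the other rdd libraries (gap 0.969). BAM5 was at 1.49 CPM in WT C and 0.486 to 0.570 in the other WT libraries (gap 0.917), and at 5.42 in rdd A and 1.41 to 2.09 in the other rdd libraries (gap 0.8294). ENT6 was at 8.43 CPM in dme D and 3.47 to 4.09 in the other dme libraries (gap 0.876). AGP2 was at 9.74 CPM in rdd D and 7.49 to 7.84 in the other rdd libraries (gap 0.845). CAT3 was at 386 CPM in dme C and 700 to 749 in the other dme libraries (gap 0.865). Total counts were 8730340 in WT B and 12143871 to 12646556 in the other WT libraries (gap 0.872), and 23302135 in rdd D and 9190099 to 11533348 in the other rdd libraries (gap 0.834). Of 155 groups of 4 libraries examined, 11 had such a gap, and chance gives about 7.75.

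Genes in which the difference between drdd and rdd departed from that between dme and WT, by the interaction test of edgeR, had positive log2 differences of 3.84 for ENT6 (adjusted p = 0.00441), 1.69 for CAT3 (0.0258), 1.15 for SAT32 (0.0192), 1.03 for AT1G06640 (0.0192) and 0.96 for AOC4 (0.0200). Negative differences were −5.73 for CYP706A6 (adjusted p = 9.57e-07), −4.80 for AT5G22860 (0.00140), −4.32 for AGP2 (0.0139), −3.92 for AT4G01490 (0.0221), −3.35 for AT2G33830 (0.00441) and −3.03 for MAF5 (0.0192). A trait of a single line would also give an interaction, so these differences are not shown to follow from DME loss itself.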

How the results depend on the processing

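The fits without dme C and rdd B were chosen after the data were seen, and the other alternatives were planned. For single named genes the size factors, the filter, DESeq2, the compared libraries, the block and each library left out were varied: none of the 118 results reversed, and of the 105 that were called, 43 passed under every one of these. DESeq2's size factors in edgeR (2, 204, 254, 86, 431 and 20 calls in the order dme, rdd and drdd against WT, drdd against rdd, drdd against dme, interaction), no count filter (2, 176, 243, 68, 340 and 18), nuclear genes only, and leaving out genes near the mutated loci (2, 134, 181, 76, 323 and 17) kept each count within 1.5 times. DESeq2, fitted to all 15 libraries, called 9, 618, 643, 372, 992 and 186 genes in the same order. With only the compared libraries in edgeR there were 0 calls for dme, 111 for drdd against WT, 50 for drdd against rdd and 134 for drdd against dme. For dme, 841 genes had an unadjusted p under 0.05 in edgeR's fit of all libraries, a smaller share than no difference would give. The fit of only the compared libraries was not run for the interaction, where it is the same fit. A fold threshold of 1 on the log2 scale, which removes calls by construction, left 110, 165, 54 and 219 calls for rdd against WT, drdd against WT, drdd against rdd and drdd against dme. Without dme C and rdd B there were 504 calls for rdd against WT and 134 for drdd against rdd. Leaving out single libraries gave 2 to 3 calls for dme, 93 to 327 for rdd, 105 to 318 for drdd against WT, 19 to 126 for drdd against rdd, 126 to 494 for drdd against dme and 6 to 45 for the interaction. The cause was not tested, except that fits with fewer libraries have fewer residual degrees of freedom.

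With the replicate letter as a block there were 111 calls for rdd against WT, 139 for drdd against WT, 50 for drdd against rdd, 225 for drdd against dme and 12 for the interaction, and 2 for dme. The letters do not pair the libraries: 8 of 21 same-letter pairs had a correlation of deviations over 0.1 (range −0.495 to 0.430), and 3 of 15 libraries correlated best with a library of their own letter. Under the block 37 of the 38 list calls remained past the threshold. Under every fit that left out 1 library 18 of the 38 did, and 2 did with an estimated correlation.

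Calls near the mutated loci stood at 2.35 times the share of tested genes for rdd against WT at 2 Mb, and at 2.46 times at 1 Mb (permutation by circular shifts, p = 0.0572) and 1.92 times at 5 Mb (p = 0.0833), past the threshold only at 2 Mb; of the 64 calls at 2 Mb 24 lay near ROS1, 37 near DML2 and 3 near DML3, the last under the share over all tested genes. For drdd against WT and drdd against dme the ratio passed only at 1 Mb (1.94 times, permutation p = 0.0310, and 1.96 times, p = 0.00480). With the WT libraries divided, rdd and drdd shared 40 calls when rdd was compared with WT A and B, 32 with C and D, 57 with A and C, 52 with B and D, 41 with A and D and 34 with B and C, against 88 undivided, with fewer libraries in each comparison. The rdd calls depended strongly on the WT libraries used. Against WT A and C there were 463 higher and 676 lower, of which 4 were called in the opposite direction in drdd. Against WT B and D there were 19 higher and 51 lower. The dme calls shared 0 with rdd and 0 with drdd when dme was compared with WT A and D, and 1 in the other divisions. Simulated 2-fold changes were found in 16.4% (interaction) to 55.2% (dme against WT) of genes, a limit set by the depth, spread and number of these libraries together.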

Other observations

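The permutation tests of list means other than that of the salicylic acid list, the comparison of rdd against WT with drdd against dme, and the counts over other divisions of the libraries were chosen after the results were seen.

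Mean levels of cell type lists were compared between genotypes library by library. The stomatal lineage list had means of 0.309 to 1.501 log2 CPM in WT, 0.425 to 1.88 in dme, 1.90 to 2.65 in rdd and 2.04 to 3.18 in drdd, so that every rdd and drdd library lay above every WT and dme library. Its exact permutation p over the 4 genotypes was 0.003209 (0.0401 adjusted over 25 lists), and 71.2% of the variance lay between genotypes. The demethylase list also passed (adjusted p = 0.00758). The trichome and epidermis list had group means of 2.03, 2.04, 3.19 and 2.98 in WT, dme, rdd and drdd (exact permutation p = 0.0251, adjusted 0.157), the xylem list 2.73, 2.76, 3.51 and 3.52 (p = 0.0468 exact, adjusted 0.234), and the floral promoters 3.06, 3.05, 3.03 and 3.45 (p = 0.0204 exact, adjusted 0.157), so these did not pass the correction.

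The other lists did not pass in camera in any contrast, which does not show that they did not change. The methylation and RdDM machinery had list medians between −0.01 and 0.08 over the 6 contrasts, and base excision repair genes between −0.11 and 0.01. The floral repressors had medians between −0.13 and 0.03, and the FLC regulators between −0.07 and 0.04. Medians were −0.17 to 0.19 for photosynthesis genes, −0.04 to 0.29 for the clock, −0.34 to 0.35 for senescence, 0.04 to 0.58 for heat shock, −0.51 to 0.42 for flavonoid synthesis, −0.14 to 0.12 for phloem, −0.03 to 0.74 for trichomes and epidermis, and −0.17 to 0.00 for reference genes. Of the shoot meristem list KNAT6 was measured (−0.33 to 0.32), and of the floral organ list SEP1 and SEP4 (medians −0.51 to 0.68). Of 12 imprinted and seed-expressed DME targets none passed the count filter; over all 15 libraries FWA had 0 counts, MEA 18, SDC 20 and PHE1 36.

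MRD1 and ESM1 differed widely between libraries of a genotype. MRD1 had 16.5, 0.798, 24.1 and 0.576 CPM in WT A to D, between 28.6 and 31.9 CPM in all dme libraries, and at most 0.393 CPM in each rdd and drdd library. ESM1, within 2 Mb of DML2 and chosen after its values were seen, is known as a modifier of glucosinolate breakdown. It had 1490 to 2653 CPM in WT, 1221 and 1401 CPM in dme A and B, 119 CPM in both dme C and dme D, 70.3 to 188 CPM in rdd and 13.9 to 24.8 CPM in drdd. Its log2 fold change was −4.16 in rdd (adjusted p = 0.0213) and −6.77 in drdd (adjusted p = 0.00444) against WT, and −1.64 in dme (adjusted p = 0.974).

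The effect of ROS1, DML2 and DML3 loss can be read from rdd against WT and from drdd against dme, which share no library. They had 27 higher and 53 lower genes in common, where independent lists of these sizes give 0.708 and 1.65. Near ROS1, DML2 and DML3, 60 of the 64 calls of rdd against WT had the same sign in drdd against dme (93.8%) and 29 were called there. Elsewhere this held for 114 of 136 (83.8%), of which 51 were called.

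Each count of calls was set beside the counts from other divisions of the same libraries into groups of the same sizes. For dme against WT, 4 of 35 divisions gave at least the 2 calls of the real one, with 45 as the highest other, so chance is not excluded; that division put WT A, WT C, dme B and dme D together. For rdd against WT, 2 of 35 divisions gave at least 200 calls, with 232 as the highest other (WT A, WT C, WT D and rdd B together), so chance is not excluded for this count. For drdd against WT 1 of 35 reached 251 calls, the real one (highest other 190). For drdd against rdd 1 of 35 reached 87 (highest other 1), and for drdd against dme 1 of 35 reached 420 (highest other 57). A share of 1 in 35 is the smallest that these divisions can give. Chance is therefore argued against for these counts but not excluded. For the interaction 3 of 100 drawn divisions gave at least 20 calls, the real one included. The others gave 495 and 80 calls, far above the real count, so chance is not excluded and the count carries little weight. Divisions that call several times the real count, as for dme and for the interaction, point to a structure of the samples apart from genotype. The first principal component held 34.4% of the variance, with WT A at 77.4, WT C at 49.7 and dme C at 52.0, and with WT B at −25.6 and WT D at −21.1.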
